A study of Sorghum bicolor with 9 samples.

How the data were processed

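Leaves of sorghum were sampled at 3 water levels, normal supply (control), mild drought and severe drought, with 3 libraries per group, as total RNA in strand-specific libraries. Each of the 9 deposited samples was used, and its group and number were taken from its label. The authors deposited read counts per gene, read counts per lncRNA transcript, and FPKM (fragments scaled by transcript length and library size) per gene and per lncRNA transcript. Per the file headers the counts and the FPKM values are separate tables with 1 column per sample, and all counts were whole numbers. Per the submitters' processing notes HISAT2 2.0.4, STAR and StringTie 1.3.3b were used; the notes as held here give no role for each, and the genome build is not given in the sources used here. Descriptions and positions of genes and transcripts were taken from the deposited tables. The supplied table of locus tags and symbols could not be matched to the gene identifiers of the files and was not used.

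The gene count table had 44775 entries, of which 34366 were in the deposited mRNA FPKM table; these are called genes here and were tested. The others were mostly lncRNA loci, and 2594 were in neither FPKM table (1438 with ENSRNA identifiers and 1156 assembled loci). Gene counts included reads of lncRNA transcripts with the same identifier: none of 95985 values of lncRNA counts exceeded that of its gene, and in the 2850 genes concerned lncRNA transcripts held a median of 12.8% of the count. In 674 of these genes they held more than 50%. The 11928 lncRNA transcripts carried the submitters' name classes LINC (8130), AS (2028), OT (1025), IT (734) and T (11), which were not interpreted. A single transcript, TCONS_00022715 (chromosome 10, 54687687 to 54688042), held 40.7% of all lncRNA counts.

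The gene table held 39573043, 33399928 and 41228478 counts in the control libraries and 34247661, 41223255 and 30926898 in mild drought. In severe drought it held 35915894, 31104925 and 27854146 counts. Genes with at least 1 count numbered 22337 (mild drought 1) to 29760 (control 2), with 28676 in mild drought 2 and at most 25066 in the others. LncRNA transcripts with at least 1 count numbered 5340 (severe drought 1) to 10024 (control 2). Counting error was small beside the spread between libraries for genes above 5 CPM, so the precision was set by that spread, with a common biological coefficient of variation of 0.503 for genes.

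Genes and lncRNA transcripts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with all 9 libraries in 1 fit and no covariate, after filterByExpr with default settings and TMM scaling. The factors ranged from 0.807 to 1.12. A result was called at a Benjamini-Hochberg adjusted p under 0.05. Effective library sizes of the lncRNA table were those of the gene table of the same libraries. The comparisons were mild drought against control, severe drought against control and severe against mild drought. After filtering, 22080 genes and 4843 lncRNA transcripts were tested. The count of genes at an unadjusted p under 0.05 is given beside the number that a uniform p would give. Fold differences of transcripts with 0 counts in a group were bounded with a floor of 3 counts over the group, and intervals of ratios of counts came from the exact binomial method at 95%.

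Before the data were examined, 32 gene lists were written as search patterns. They covered late embryogenesis abundant and dehydrin proteins, heat shock proteins, abscisic acid synthesis and signalling, proline, raffinose and trehalose, and aquaporins. They further covered antioxidant enzymes, class III peroxidases, glutathione S-transferases, photosystems, C4 enzymes, the Calvin cycle, chlorophyll synthesis and breakdown, ribosomal proteins, histones, and cell wall loosening and synthesis. The remaining ones were NAC, WRKY and AP2/ERF factors, ethylene, jasmonate and auxin, defence proteins, sugar transport and starch, nitrogen assimilation, cuticular wax, guard cell and vascular markers and the circadian clock. Membership was decided by the Swiss-Prot protein name in the deposited description, which 20947 genes had. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and adjusted over 96 tests. Medians of lists are of these log2 CPM values, and numbers of members above or below 0 are by the log2 differences of edgeR unless stated otherwise. Members were also adjusted over the list alone, using the p-values of edgeR.

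Genes to be named were fixed by a rule, also chosen before the data were examined. It took, in each comparison, up to 6 genes that rose most and 6 that fell most among called genes with a named function, a mean of at least 5 CPM and groups that did not overlap. It also took up to 4 members with the smallest p of each described list, and fixed members of proline, dehydrin, abscisic acid synthesis and C4 genes. Members that passed when adjusted over the list alone were named as well, which was not part of the rule as first written. For lncRNA transcripts the minimum mean was 1 CPM and up to 4 were taken per direction. As edgeR called 0 genes at this threshold, with 1414, 1914 and 815 at an unadjusted p under 0.05, the same rule was applied to the 190, 311 and 16 genes called by DESeq2 1.42.0 in the 3 comparisons, a step added after that result was seen.

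Overlap between the drought levels was set against independent lists and against 10 simulations of unchanged groups with shared controls. Each lncRNA transcript was paired with the nearest tested gene, and the Spearman correlation of log2 differences in severe drought was set against 10000 permutations. Principal components were computed from log2 CPM centred per gene.

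The tests were tried on simulated data with the measured means and dispersions, in which 200 genes were changed 2, 4 or 8-fold, and again at a hundredth of the dispersion. In the lists test 3 lists raised 1.5-fold were called and 0 unchanged lists were. Genes were simulated independently of each other in these tests. They could therefore not show false calls that arise from correlation between members of a list. Nor could they show those from differences between libraries that crossed the water levels.

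Alternatives chosen before the data were examined were DESeq2, RLE scaling, no filter, a mean of at least 1 CPM, only the 6 libraries compared, the label number as a block, an absolute log2 difference of at least 1 in addition, and limma-trend on log2 FPKM with 0.1 or 1 added. Others were the lncRNA table's own totals, camera with an estimated correlation, fry, leaving out each library in turn, nearest genes within 10 kb, and 1 pair per lncRNA gene. Alternatives added later were all entries of the gene table, gene counts minus lncRNA counts, voom with and without sample quality weights, 1 surrogate variable from sva 3.50.0, lncRNA counts summed per gene identifier, membership by the whole description, leaving out each library with the genes that pass the filter with all 9, and nearest genes without pairs of the same identifier. Other splits of the 6 or 9 libraries were tested in the same way as the real groups, those of the 9 with a limma-trend F test on log2 CPM. No per-sample column was left unused; FPKM values entered only the alternatives, since a test on counts keeps the counting error.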

Results

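Leaves of sorghum (Sorghum bicolor), a C4 cereal grown in dry regions, were profiled by strand-specific sequencing of total RNA at 3 levels of water supply. The groups were normal supply (control), mild drought and severe drought, with 3 libraries each. Both genes and long non-coding RNAs (lncRNAs, long transcripts without a recognised coding sequence) were counted. The labels do not say whether the libraries of a group came from separate plants, and p-values here measure only the spread between these samples, which may be technical. Counts over the gene table ranged from 27854146 in severe drought 3 to 41228478 in control 3. Of these, 20772692 to 38711314 fell on the 34366 genes of the mRNA table. The 11928 lncRNA transcripts had 1213470 to 2902522 counts. Levels are given as scaled counts (CPM, counts relative to the effective library size), as mean ± SD over 3 libraries, and differences as log2 values ± SE. Positions are those of the deposited tables, whose genome build is not given in the sources used here. They cover whole gene models without exons or untranslated regions.

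The largest component of the differences between libraries did not follow the water supply. The second placed the severe drought libraries below all others, and the third followed the supply in part. The first principal component held 28.7% of the variance and set control 3, mild drought 2, severe drought 1 and severe drought 2 (coordinates 28.7 to 123) apart from the other 5 libraries (-61.7 to -46.2). On the second component, with 17.8% of the variance, severe drought 1 lay farthest out at -127. Severe drought 2 and 3 (-18.4 and -15.6) also lay below the controls (26.5 to 45.9) and the mild drought libraries (2.35 to 50.2). The third, with 15.3%, placed the controls at -63.5, -43.4 and -29.7 and the drought libraries at -9.67 to 74.9, except severe drought 1 at -45.5. Correlations of log2 CPM between libraries of 1 group had a median of 0.914 (9 pairs, 0.866 to 0.952), and those between groups a median of 0.911 (27 pairs, 0.85 to 0.942). The common biological coefficient of variation was 0.503 for genes and 0.858 for lncRNA transcripts. In severe drought 1 alone, 64 genes had no count although each had at least 5 CPM in all 8 other libraries, while no other library lacked more than 1 gene in this way. Among them was the receptor kinase-like protein Xa21 (SORBI_3004G214900, chromosome 4, 56475667 to 56479665), of a family that perceives microbes, with a mean of 567 CPM in the other libraries (252 to 882).

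**Figure D1:**
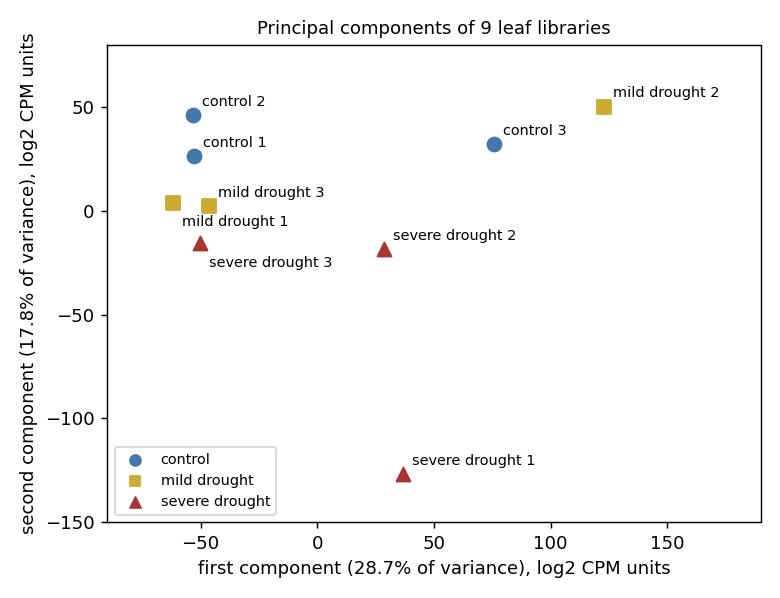
Each point is 1 library, placed by its first and second principal component of log2 CPM over the tested genes, with the group shown by colour and shape. Control 3 (75.9) and mild drought 2 (123) lie at the right and severe drought 1 (-127) at the bottom. The 3 severe drought libraries lie below 0 on the second component and the others above it. Control and mild drought overlap, so the 3 groups do not form separate clusters on these 2 components.

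**Figure D2:**
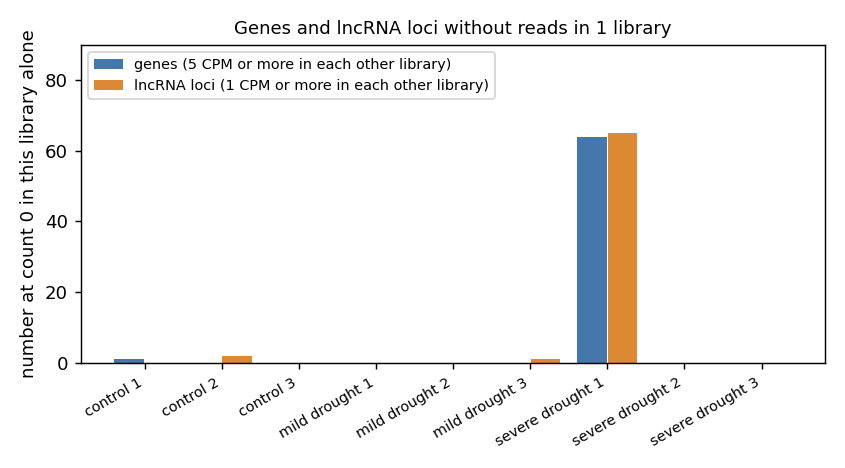
Bars give, for each of the 9 libraries, the number of genes (5 CPM or more in each other library) and of lncRNA loci (1 CPM or more in each other library) with a count of 0 in that library alone. Severe drought 1 has 64 genes and 65 lncRNA loci, and the other libraries have at most 1 and 2.

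Mild drought was first set against the control, to ask which genes respond when water is moderately short. Both P5CS genes of proline synthesis, the dehydrin gene DHN1, 6 of 35 abscisic acid signalling genes and a pair of beta-amylase genes were higher, and an abscisic acid receptor and a sugar exporter were lower, each when adjusted over the list alone. That adjustment does not cover the 32 lists searched, and none of these genes passed over all genes in edgeR. Delta-1-pyrroline-5-carboxylate synthase 2 (P5CS2, SORBI_3003G356000, chromosome 3, 67427644 to 67434548), an enzyme of proline synthesis from glutamate, had 16.5 ± 0.709 CPM in the control. In mild drought it had 225 ± 152 CPM, which is a 13.6-fold difference (log2 3.77 ± 0.46). Its adjusted p was 0.24 over all genes in edgeR, 0.000195 over the list alone and 4.46e-13 in DESeq2. Its paralog P5CS1 (SORBI_3009G160100, chromosome 9, 51779375 to 51800133) went from 34.1 ± 2.09 to 110 ± 33.4 CPM (log2 1.69 ± 0.26). Dehydrin DHN1 (SORBI_3009G116700, chromosome 9, 45915615 to 45916682) belongs to a family of hydrophilic proteins that accumulate in drying cells. It had 0.682 ± 0.564 CPM in the control and 31.6 ± 14.4 in mild drought (log2 5.52 ± 0.85, adjusted p = 0.000624 over the list alone). In all 3 of these genes every mild drought library lay above every control library. With 3 libraries against 3, chance parts the groups, in either direction, in 10% of genes. Of the other measured genes described as dehydrins, SORBI_3004G286600 had 13.5 ± 1.76 CPM in the control and 8.47 ± 1.57 in mild drought (log2 -0.68 ± 0.24), and SORBI_3003G270200 had 0.0784 ± 0.136 and 0.63 ± 0.562 CPM. Neither passed in edgeR over all genes (adjusted p = 0.718 and 0.868).

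Among 35 measured abscisic acid receptors, type 2C phosphatases, kinases and response factors, 6 rose and 1 fell in mild drought when adjusted over the list alone, and 28 did not pass. Probable protein phosphatase 2C 68 (SORBI_3002G172000, chromosome 2, 54480172 to 54484180) rose from 6.04 ± 2.3 to 35.3 ± 14.1 CPM (log2 2.55 ± 0.50). The phosphatases 2C 37 (SORBI_3006G018400) and 2C 30 (SORBI_3001G424400) rose 10.2-fold and 8.23-fold. Enzymes of this class hold back the hormone's signal. The receptor PYL4 (SORBI_3001G403300, chromosome 1, 68842276 to 68843883) fell from 27.8 ± 6.98 to 5.35 ± 3.04 CPM (log2 -2.38 ± 0.41, adjusted p = 0.0093 over the list alone). In the list of sugar transport and starch, with 76 measured members, 3 rose and 1 fell when adjusted over the list alone. The plastid starch-degrading enzyme beta-amylase 1 (SORBI_3001G226600, chromosome 1, 21690596 to 21694416) rose from 2.47 ± 3.1 to 83.8 ± 47.6 CPM (log2 5.07 ± 1.01). Beta-amylase 2 (SORBI_3001G508800) rose 2.25-fold. SWEET16 (SORBI_3001G377600) had no count in the control libraries and 0.953 ± 0.554 CPM in mild drought. SWEET13 (SORBI_3008G094400), which exports sucrose from leaf cells, fell from 78.2 ± 9.32 to 38.7 ± 6.51 CPM. A malic enzyme gene of the Calvin cycle list (SORBI_3003G292400), which releases carbon dioxide from malate, rose from 0.0676 ± 0.117 to 3.75 ± 1.96 CPM when adjusted over the list alone. The more abundant NADP-dependent malic enzyme genes did not pass, with 3046 ± 707 CPM in the control and 2468 ± 1168 in mild drought (SORBI_3003G036200), 434 ± 51.9 and 363 ± 34 (SORBI_3009G108700), and 247 ± 76.9 and 124 ± 32.9 (SORBI_3003G280900).

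**Figure D3:**
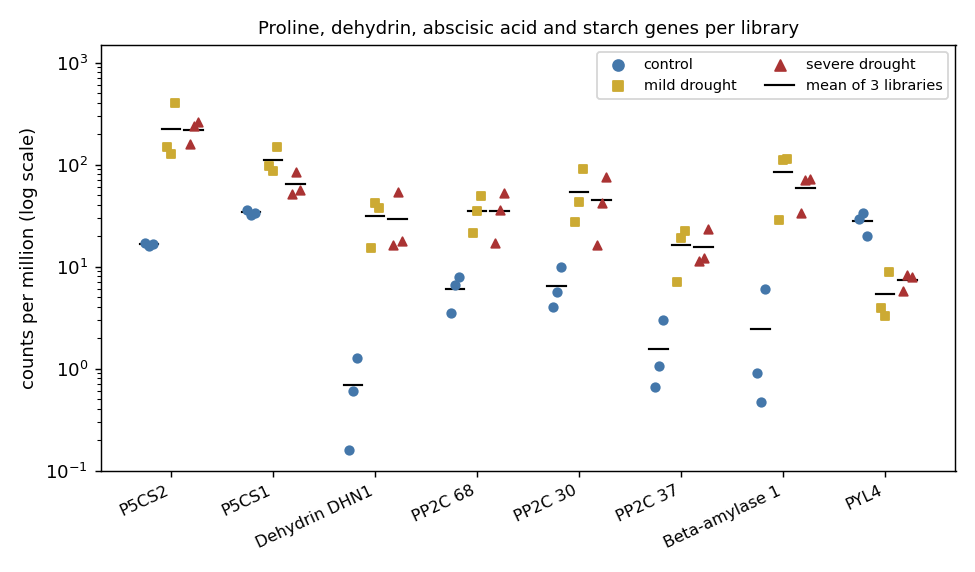
CPM on a log scale in each of the 9 libraries for 8 genes of proline synthesis, dehydrins, abscisic acid signalling and starch breakdown, with horizontal lines at the means of 3 libraries per group. P5CS2 lay between 15.8 and 17.1 in the control libraries and between 127 and 400 in the 6 drought libraries, while PYL4 was lower in all 6.

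Of the 32 gene lists chosen before the data were examined, 4 passed camera at an adjusted p under 0.05 in mild drought. Medians of lists are of log2 CPM, as tested by camera, while numbers of members above or below 0 are by the log2 differences of edgeR, and the 2 measures can differ in sign for genes with few counts. The 236 ribosomal proteins, the protein part of the translation machinery, were shifted up as a list, with 198 above 0 and a median of 0.21 (adjusted p = 1.24e-06). With an estimated correlation the adjusted p was 0.92. The genes of 60S proteins L18a-like (SORBI_3009G233300) and L32-1 (SORBI_3002G255100) had log2 differences of 0.68 ± 0.23 and 0.58 ± 0.20. None of the list's members passed alone, and some are named 30S or 50S proteins, which belong to organelle ribosomes. The 5 measured late embryogenesis abundant and dehydrin proteins were shifted up as a list, with 4 above 0 and 1 below. Their median was 1.79 (adjusted p = 0.00697, and 0.613 with an estimated correlation). Among them DHN1 passed when adjusted over the list alone. The WRKY transcription factors, many of which act in defence and senescence, were shifted down, with 41 of 68 below 0 and a median of -0.25 (adjusted p = 0.0157; adjusted p = 0.613 with an estimated correlation). WRKY24 (SORBI_3009G100500, chromosome 9, 39826393 to 39831148) fell from 93.1 ± 14.4 to 47.3 ± 3.22 CPM when adjusted over the list alone (adjusted p = 0.0306). Heat shock proteins and their factors were shifted up (44 of 77 above 0, median 0.11, adjusted p = 0.0241; adjusted p = 0.92 with an estimated correlation). A heat shock 70 kDa protein (SORBI_3003G350700) rose from 35.1 ± 12.9 to 116 ± 8.3 CPM when adjusted over the list alone. Mean levels of the ribosomal, heat shock and WRKY lists overlapped between the groups. Ribosomal proteins stood at -0.0363 in mild drought 3 and 0.126 in control 1, and heat shock proteins at -0.122 in mild drought 1 and 0.0881 in control 2. WRKY factors stood at 0.336 in mild drought 2 and 0.209 in control 3. Without control 3 the ribosomal and heat shock lists did not pass (0.142 and 0.156). The heat shock list also did not pass without mild drought 3 (0.0936), the WRKY list without control 2 (0.164) and the dehydrin list without mild drought 2 (0.0902). With the genes that passed the filter with all 9 libraries, the heat shock list also did not pass without mild drought 2 (0.0569), nor the WRKY list without mild drought 3 (0.107). The medians also moved on these genes, between 1.13 (without control 2) and 2.27 (without control 3) for the dehydrin list, 0.10 and 0.31 for ribosomal proteins, 0.05 and 0.28 for heat shock proteins and -0.37 and -0.11 for WRKY factors.

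Over all 22080 tested genes, edgeR called 0 genes in mild drought against control, with 1414 at an unadjusted p under 0.05 where 1104 would be expected. The lowest adjusted p was 0.24. DESeq2 called 190 (113 up, 77 down). Besides the genes above, the rule for named genes applied to the DESeq2 calls, a step added after the edgeR count was seen, gave the following genes. By DESeq2, indole-2-monooxygenase (SORBI_3007G003400, chromosome 7, 315339 to 321801), a cytochrome P450 of indole metabolism, rose from 8 ± 4.94 to 72.9 ± 29.3 CPM (adjusted p = 4.54e-07). Extracellular ribonuclease LE (SORBI_3002G278700) rose from 0.808 ± 0.775 to 20.3 ± 24.2 CPM and chloride channel protein CLC-a (SORBI_3010G214600) from 2.31 ± 0.927 to 29 ± 37.1 CPM by DESeq2 (adjusted p = 0.00375 and 0.0231), with an SD above the mean in mild drought for both. Cell number regulator 7 (SORBI_3001G024500) fell from 286 ± 124 to 79.1 ± 25.3 CPM by DESeq2 (adjusted p = 0.011). Ethylene-responsive transcription factor 1A (SORBI_3004G297100), a WAT1-related protein (SORBI_3003G184100), an ABC transporter of the G family (SORBI_3004G087800) and a cysteine-rich receptor-like kinase (SORBI_3002G327800) fell by DESeq2 as well. On data simulated with the measured spread, edgeR found 50.7% of genes changed 4-fold in this comparison with 1 unchanged gene called. DESeq2 found 86.6% with 70 unchanged genes called. In this and the other comparisons genes were simulated independently, without differences between libraries that crossed the water levels. The shares found and the false calls may therefore differ in the real data. Another split of these 6 libraries (control 3, mild drought 2 and mild drought 3 together) gave 856 genes in DESeq2. When mild drought 3, whose P5CS2 level was 400 CPM, was left out, edgeR called 1 gene, P5CS2 itself, with a log2 difference of 3.06 and an adjusted p of 0.0432.

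Severe drought was next compared with the control, to ask which genes respond at the strongest shortage. P5CS2, DHN1 and the phosphatase 2C 68 had means near those in mild drought, while the mean of P5CS1 was lower than there. P5CS2 reached 220 ± 54.9 CPM (log2 3.73 ± 0.46; adjusted p = 0.214 over all genes in edgeR, 0.000208 over the list alone and 9.16e-13 in DESeq2). P5CS1 reached 64.3 ± 17.6 CPM (log2 0.92 ± 0.26, adjusted p = 0.0282 over the list alone). Proline dehydrogenase 2 (SORBI_3001G304700, chromosome 1, 58850919 to 58854469), which degrades proline, fell from 82.8 ± 26.3 to 26.4 ± 6.33 CPM. Of the 9 proline genes 2 rose and 1 fell when adjusted over the list alone. DHN1 stood at 29.3 ± 21.4 CPM (log2 5.41 ± 0.85). The late embryogenesis abundant proteins 31 (SORBI_3007G109800) and D-34 (SORBI_3004G142500) rose 5.42-fold and 5.03-fold. Thus 3 of 5 measured members rose when adjusted over the list alone.

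In the abscisic acid signalling list, 3 phosphatases rose and PYL4 fell in severe drought when adjusted over the list alone, and 31 of 35 members did not pass. Phosphatase 2C 68 stood at 35.1 ± 18 CPM, and PYL4 at 7.33 ± 1.41 CPM (log2 -1.92 ± 0.40). Beta-amylase 1 rose to 59.1 ± 21.9 CPM and SWEET13 fell to 42 ± 6.15 CPM when adjusted over the list alone, the only 2 of 76 members of the sugar and starch list to pass. In the list of cellulose and lignin synthesis, with 83 members, 1 rose and 1 fell when adjusted over the list alone. Laccase-10 (SORBI_3001G422300, chromosome 1, 70308577 to 70311856), of an enzyme family that polymerises lignin, rose from 0.604 ± 0.182 to 16.9 ± 13.9 CPM. Cellulose synthase-like protein E2 (SORBI_3004G255200) fell from 16 ± 4.56 to 4.91 ± 1.29 CPM. Among 22 genes of nitrogen assimilation, the high-affinity nitrate transporter 2.3 (SORBI_3003G270800, 2.41 ± 0.375 to 0.512 ± 0.254 CPM) and an asparagine synthetase (SORBI_3010G110000, 45.4 ± 7.12 to 26.2 ± 0.888 CPM) fell when adjusted over the list alone. Of 47 glutathione S-transferases, detoxifying enzymes, 2 rose and 2 fell when adjusted over the list alone. Among them GSTU6 (SORBI_3003G187000) rose 3.09-fold. Auxin-responsive protein IAA31 (SORBI_3002G055900) rose 2.44-fold and autophagy-related protein 18b (SORBI_3004G327100) fell from 19.8 ± 0.554 to 9.73 ± 1.54 CPM, the only members of the auxin and of the chlorophyll breakdown and senescence lists to pass when adjusted over the list alone.

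In severe drought 5 lists passed camera. Photosystem and light-harvesting genes were shifted up, with 58 of 66 above 0 and a median of 0.55 (adjusted p = 1.6e-06; adjusted p = 0.843 with an estimated correlation), although no member passed alone. The groups overlapped, since the list's mean level was 0.503 and 0.698 in severe drought 1 and 2 but -0.0131 in severe drought 3, below control 3 (0.307). When 1 library was left out the list still passed, but its median lay between 0.25 (without control 2) and 0.82 (without severe drought 3). WRKY factors were shifted down, with 51 of 68 below 0 and a median of -0.42 (adjusted p = 0.00264; adjusted p = 0.613 with an estimated correlation). The list's mean level was lower in each of the 3 severe drought libraries (-0.334 to -0.216) than in each control library (0.209 to 0.535). Ribosomal proteins were shifted up by a median of 0.12 (167 of 236 above 0, adjusted p = 0.00432; adjusted p = 0.92 with an estimated correlation). So was the list of 5 late embryogenesis abundant and dehydrin proteins, though only 3 were above 0 and 2 were below. Its median was 2.42 (adjusted p = 0.00704, and 0.613 with an estimated correlation). Heat shock proteins were shifted up as well (47 of 77 above 0, median 0.30, adjusted p = 0.0157, and 0.92 with an estimated correlation). Mean levels of the heat shock list overlapped between the groups, with severe drought 1 and 3 (-0.165 and -0.122) below control 2 (0.0881). Those of the ribosomal list did as well (-0.155 in severe drought 2 and 0.126 in control 1). Heat stress transcription factor C-2a (SORBI_3004G101400) rose from 1.66 ± 0.396 to 9.73 ± 5.97 CPM when adjusted over the list alone. The ribosomal list did not pass without control 3 (0.771) or severe drought 3 (0.344), and the heat shock list did not pass without control 3 (0.142) or severe drought 2 (0.125). The dehydrin list did not pass in 7 of the 9 fits that left out 1 library, those without control 1, control 2, control 3, mild drought 1, severe drought 1, severe drought 2 or severe drought 3 (0.203, 0.183, 0.116, 0.278, 0.188, 0.254 and 0.204). Those 7 fits tested 9 members against 5, because more genes with few counts passed the filter, so the list was not the same and its median lay between -0.12 and 0.30. With the genes that passed the filter with all 9 libraries, it passed in all 9 fits (highest adjusted p = 0.0297, without control 2), with medians of 1.81 to 3.02. On these genes the medians lay between 0.18 and 0.34 for heat shock proteins and between -0.55 and -0.36 for WRKY factors, and that of ribosomal proteins was 0.00 without control 3.

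**Figure D4:**
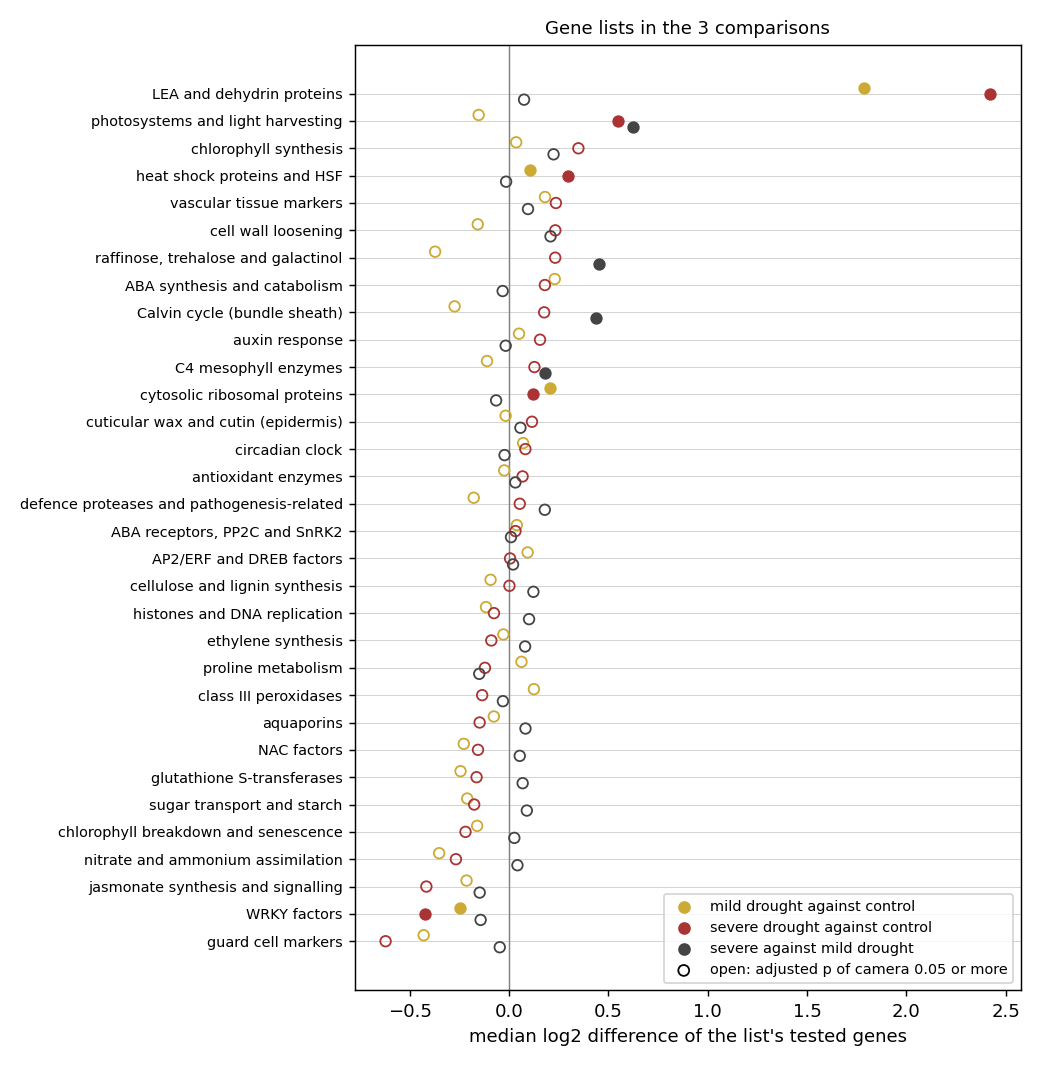
Median log2 difference of the tested genes of each of the 32 lists (horizontal axis) in the 3 comparisons, shown by colour; filled points have an adjusted p of camera under 0.05 with the preset correlation. Filled points number 4 in mild drought, 5 in severe drought and 4 between the drought levels, and none was filled with an estimated correlation.

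Over all genes, edgeR called 0 in severe drought against control, with 1914 at an unadjusted p under 0.05 (1104 expected) and a lowest adjusted p of 0.214. DESeq2 called 311 (153 up, 158 down). The enzyme named P-(S)-hydroxymandelonitrile lyase (SORBI_3004G335500, chromosome 4, 66773685 to 66780194) acts in the release of cyanide from the sorghum glucoside dhurrin. It rose from 73.1 ± 96.4 to 2018 ± 1398 CPM by DESeq2 (log2 4.79 ± 1.16, adjusted p = 4.73e-05). The chloride channel protein CLC-a (SORBI_3010G214600) rose from 2.31 ± 0.927 to 95.9 ± 106 CPM and bZIP transcription factor 53 (SORBI_3004G031100) from 0.144 ± 0.0217 to 11.6 ± 10 CPM by DESeq2. The enzyme 5'-methylthioadenosine/S-adenosylhomocysteine nucleosidase (SORBI_3003G007800) rose from 1.3 ± 2.05 to 276 ± 275 CPM by DESeq2 (adjusted p = 0.0213). Beta-glucosidase 18 (SORBI_3006G146100, 166 ± 181 to 11.4 ± 6.55 CPM) and mannan endo-1,4-beta-mannosidase 3 (SORBI_3001G027800, 9.11 ± 5.44 to 1.2 ± 0.903 CPM) fell by DESeq2. Lipid phosphate phosphatase 2 (SORBI_3009G221500, 11.5 ± 4.37 to 1.47 ± 0.658 CPM), mitochondrial calcium uniporter protein 2 (SORBI_3001G449100, 12.7 ± 5.97 to 1.42 ± 0.271 CPM) and 2 genes named wall-associated receptor kinase 5 (SORBI_3007G214300 and SORBI_3002G021900) fell by DESeq2. On simulated data edgeR found 47.8% of genes changed 4-fold here with 3 unchanged genes called, and DESeq2 79.1% with 62. Without mild drought 3, or with only the 6 libraries compared, edgeR called P5CS2 (adjusted p = 0.00835 and 0.0307). In the second of these fits it also called pectinesterase inhibitor 10 (SORBI_3001G198700, log2 3.11).

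Severe drought was then compared with mild drought, to ask what further shortage adds. Lists of photosynthesis genes and of raffinose and trehalose metabolism were shifted up in severe drought with the preset correlation of camera, but not with an estimated correlation (adjusted p = 0.613 for photosystems and for raffinose). P5CS2 and DHN1 had log2 differences of -0.04 ± 0.41 and -0.11 ± 0.69, and P5CS1 one of -0.77 ± 0.26 (unadjusted p = 0.0147, adjusted p = 0.996). Of 66 photosystem and light-harvesting genes 63 were above 0, with a median of 0.63 (adjusted p = 3.59e-10; adjusted p = 0.613 with an estimated correlation). A chlorophyll a/b-binding protein of photosystem I (SORBI_3004G308700, chromosome 4, 64612218 to 64614545) had 181 ± 35 CPM in mild and 315 ± 127 in severe drought (log2 0.80 ± 0.33). The photosystem II reaction centre W protein (SORBI_3009G191300) had 150 ± 40.6 and 263 ± 88 CPM. No member of this list passed alone, and its mean level was lower in severe drought 3 (-0.0131) than in mild drought 3 (0.014), so the groups overlapped. The 3 libraries with the highest means of the list, severe drought 2, severe drought 1 and control 3, were among the 4 set apart on the first component, while the fourth, mild drought 2, was at -0.124. The list thus partly followed a difference that crossed the water levels. When 1 library was left out and the same genes were kept, the list still passed, with medians between 0.47 and 0.88.

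Genes of raffinose, trehalose and galactinol, sugars that protect drying cells, were shifted up between the drought levels, with 21 of 26 above 0 and a median of 0.45 (adjusted p = 0.000276; adjusted p = 0.613 with an estimated correlation). In mild drought the list was below the control, though it did not pass (18 of 26 below 0, median -0.37, adjusted p = 0.249), and in severe drought it did not pass against the control (adjusted p = 0.126). Its mean level was lower in severe drought 2 (0.0173) than in mild drought 3 (0.085), so the groups overlapped. A raffinose synthase gene (galactinol-sucrose galactosyltransferase, SORBI_3003G052300) had 77 ± 16 CPM in mild and 173 ± 60.8 in severe drought, and galactinol synthase 2 (SORBI_3002G423600) had 3.12 ± 3.22 and 23.4 ± 22.8 CPM. The Calvin cycle list, whose enzymes act in the bundle sheath of C4 leaves, was shifted up with 18 of 26 above 0 and a median of 0.44 (adjusted p = 0.0171; adjusted p = 0.843 with an estimated correlation). Phosphoribulokinase (SORBI_3004G272100), which regenerates the acceptor of carbon dioxide, had 548 ± 81 and 1048 ± 438 CPM, and a chloroplastic fructose-1,6-bisphosphatase (SORBI_3001G425400) had 97.9 ± 29.7 and 166 ± 51.2 CPM. The C4 mesophyll enzymes were shifted up with 15 of 22 above 0 and a median of 0.18 (adjusted p = 0.0279, and 0.613 with an estimated correlation). The groups overlapped in both lists. Mean levels in severe drought 3 (-0.143 for the Calvin cycle and -0.085 for C4) lay below those in mild drought 3 (0.163 and 0.064). Phosphoenolpyruvate carboxylase 3 (SORBI_3010G160700, chromosome 10, 47244445 to 47253575) fixes bicarbonate in the mesophyll. It had 18030 ± 608 CPM in the control, 22670 ± 9236 in mild and 35560 ± 12800 in severe drought (log2 0.65 ± 0.59 between the drought levels). The Calvin cycle list did not pass without mild drought 1 (0.0609), mild drought 2 (0.197), severe drought 1 (0.144) or severe drought 2 (0.173). The C4 list did not pass in 7 of 9 such fits, without control 1, control 2, control 3, mild drought 1, mild drought 2, severe drought 1 or severe drought 2 (0.106, 0.067, 0.064, 0.141, 0.199, 0.159 and 0.254). These fits tested 23 or 24 members against 22. With the genes that passed the filter with all 9 libraries, both lists did not pass in 3 fits, without mild drought 2, severe drought 1 or severe drought 2 (0.201, 0.148 and 0.167 for the Calvin cycle and 0.16, 0.107 and 0.12 for C4). On these genes the medians lay between 0.22 and 0.53 for the Calvin cycle, 0.14 and 0.36 for C4 and 0.31 and 0.62 for the raffinose list, which passed in all 9 fits.

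Between the drought levels edgeR called 0 genes, with 815 at an unadjusted p under 0.05 (1104 expected) and a lowest adjusted p of 0.996. DESeq2 called 16 (2 up, 14 down). On data simulated with the measured spread, edgeR found 56% of genes changed 4-fold in this comparison with 5 unchanged genes called. DESeq2 found 82.8% with 103 unchanged genes called, which is more than the 16 called in the real data. By DESeq2, a gene named alliin lyase (SORBI_3003G277800, chromosome 3, 61364457 to 61370278) fell from 56.4 ± 16.4 to 14.1 ± 3.24 CPM (log2 -2.00 ± 0.27, adjusted p = 2.1e-06). The transporter gene ZINC INDUCED FACILITATOR-LIKE 1 (SORBI_3008G015800) fell by DESeq2 from 147 ± 2.78 to 71.5 ± 16.2 CPM. An acyltransferase-like protein (SORBI_3002G260000, 15.2 ± 3.81 to 4.02 ± 0.943 CPM) and NADH-ubiquinone oxidoreductase chain 6 (SORBI_3010G098800, 25.5 ± 18.7 to 3.08 ± 0.536 CPM) also fell by DESeq2. Of the counts of the latter, 34.2% were also counted for lncRNA transcripts. When adjusted over the list alone, aquaporin NIP4-1 (SORBI_3003G098100) fell from 1.51 ± 0.831 to 0.0227 ± 0.0393 CPM. The potassium channel gene KAT1 (SORBI_3004G107550), of the guard cell list, rose from 8.3 ± 0.595 to 22.9 ± 11.1 CPM when adjusted over the list alone. Of the counts of that KAT1 gene, 68.5% were also counted for lncRNA transcripts of the same identifier.

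The other lists did not pass camera in any of the 3 comparisons. Their lowest adjusted p was 0.0896 for jasmonate synthesis and signalling (mild drought, median -0.21) and for nitrate and ammonium assimilation (mild drought, median -0.35). It was 0.1 for chlorophyll breakdown and for sugar transport and starch (both mild drought), and 0.103 for abscisic acid synthesis (severe drought), chlorophyll synthesis (severe drought) and cell wall loosening (between the drought levels). The value was 0.131 for abscisic acid signalling, 0.148 for guard cell markers, and 0.206 for cuticular wax and cutin and for histones and DNA replication. Next came 0.261 for proline metabolism, 0.265 for auxin response, 0.28 for NAC factors and 0.287 for cellulose and lignin synthesis. For the circadian clock it was 0.348, for antioxidant enzymes 0.355, and for AP2/ERF factors and for vascular markers 0.434. Glutathione S-transferases reached 0.537, ethylene synthesis 0.596, defence proteases and pathogenesis-related proteins 0.604, aquaporins 0.81 and class III peroxidases 0.831. Median, mean and camera direction differed in sign for 8 lists in mild drought, 3 in severe drought and 10 between the drought levels, none of which passed. The 4 measured genes of 9-cis-epoxycarotenoid dioxygenase encode a committed step of abscisic acid synthesis. Of these SORBI_3001G155300 had 2.76 ± 1.41 CPM in the control, 10.2 ± 5.65 in mild and 9.09 ± 2.21 in severe drought. It rose in mild drought by DESeq2 (adjusted p = 0.0433; edgeR 0.6) and did not pass in severe drought (DESeq2 0.0717; edgeR 0.422). The other 3 did not pass, with mild drought to control ratios of 0.859 (SORBI_3002G168700), 1.01 (SORBI_3002G168800) and 0.94 (SORBI_3004G268500). The last, the most abundant, had 1210 ± 766 CPM in the control, 1137 ± 1018 in mild and 1334 ± 514 in severe drought.

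Because both drought levels were compared with the same 3 control libraries, their shared genes were counted against simulated groups. With edgeR 0 genes were called in both, since it called 0 in each comparison, with 1414 and 1914 genes at an unadjusted p under 0.05. With DESeq2, 67 genes rose in both and 38 fell in both, 105 in all, and 0 went opposite ways. Independent lists of these sizes would share 0.769 and 0.541 among 22472 genes. In 10 simulations of unchanged groups with the shared controls, a mean of 7.5 and at most 12 genes were called in both, from shorter lists with means of 42 and 37.2 genes. Genes were simulated independently of each other, without the differences between libraries that crossed the water levels. The simulations therefore cannot exclude chance for the 105 shared genes. Over all 22080 genes the log2 differences of both drought levels had a correlation of 0.575, against 0.495 in the simulations. The 3 control libraries are too few to be split between the comparisons.

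The lncRNA transcripts were tested in the same way, since the series set out to find those that respond to drought. Of 4843 tested transcripts 1 fell in severe drought in edgeR, but this call and the 4 between the drought levels ended with only the 6 libraries compared and with the label number as a block, as given below. This TCONS_00023113 (SORBI_3010G232200-OT3, chromosome 10, 57531766 to 57535282) had 8.21 ± 1.58 CPM in the control, 11.8 ± 3.45 in mild drought and no count in any of the 3 severe drought libraries (adjusted p = 0.0117). With a floor of 3 counts over the group, it was at least 198-fold lower than in the control and, in the comparison with mild drought (adjusted p = 0.00894), at least 267-fold lower. A second transcript of the same locus, TCONS_00023111 (SORBI_3010G232200-OT2, 57531727 to 57535299), had 14 counts in the control, 12 in mild and 768 in severe drought and rose between the drought levels (ratio 89.9, 95% interval 51.2 to 175; adjusted p = 0.0278). Summed over its 3 transcripts the locus had 14.4 ± 0.0309, 16.9 ± 2.41 and 17.2 ± 8.78 CPM, with log2 differences of 0.26 ± 0.44 between severe drought and control and 0.03 ± 0.44 between the drought levels. Between the drought levels TCONS_00024945 (SORBI_3002G094800-OT3, chromosome 2, 9826750 to 9828843) also fell, with 264 counts in mild and 0 in severe drought (at least 62.6-fold lower, adjusted p = 0.0278). A count of 0 also occurred in 1 library alone for an overlapping transcript of its locus that was not called. That transcript, TCONS_00024943, had 0 counts in severe drought 1 but 264 and 298 in severe drought 2 and 3. TCONS_00095547 (SORBI_3K044411-OT4, super_2942, 692 to 2564) fell from 1681 counts to 1 (mild to severe ratio 1200, 95% interval 214 to 47300; adjusted p = 0.0278), and it had 2 counts in the control. The intervals came from an exact binomial method, whose lower 95% limits for the ratios given above from the floor were 161, 217 and 50.6. Intervals and floors cover counting error only.

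**Figure D5:**
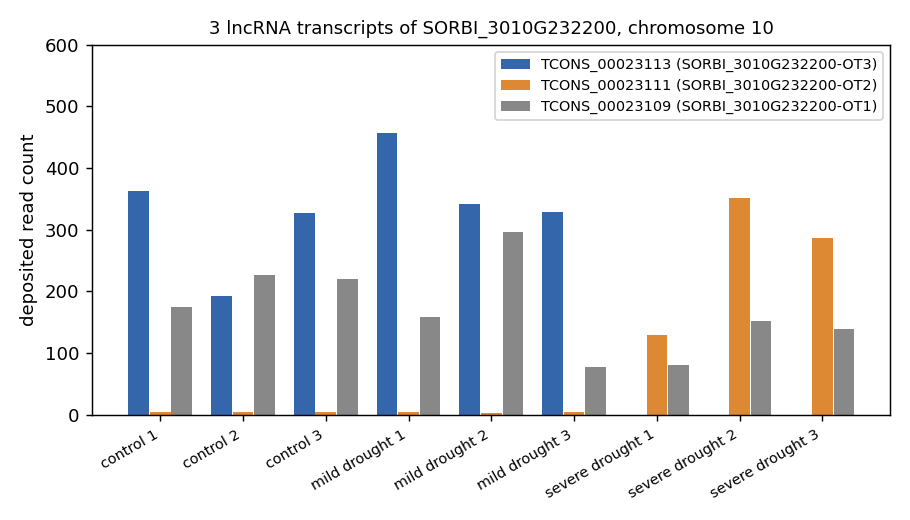
Deposited read counts (vertical axis, from 0) of 3 lncRNA transcripts of the locus SORBI_3010G232200 in each of the 9 libraries. TCONS_00023113 has between 192 and 456 counts in the control and mild drought libraries and 0 in the severe drought libraries, where TCONS_00023111 has 130, 352 and 286.

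Sums over the loci of TCONS_00024945 and TCONS_00095547 did not pass either (log2 -0.38 ± 0.46 and -1.20 ± 0.99 between the drought levels, adjusted p = 0.998 for both). With only the 6 libraries compared, the adjusted p of TCONS_00023113 was 0.141 against the control and 0.143 between the drought levels, and that of TCONS_00024945, TCONS_00023111 and TCONS_00095547 was 0.192, 0.151 and 0.0801. With the label number as a block these values were 0.221, 0.185, 0.461, 0.374 and 0.256. The call of TCONS_00023113 against the control ended without control 1, control 2, control 3, mild drought 1 or mild drought 3 (0.0825, 0.0613, 0.0804, 0.0682 and 0.0841). Its call between the drought levels ended without control 1, mild drought 1 or mild drought 3 (0.0556, 0.0635 and 0.0622). The calls of TCONS_00024945 and TCONS_00023111 held only without severe drought 1 (0.0355 and 0.0125) and that of TCONS_00095547 only without control 3 (0.0475). In the other 8 fits of each the adjusted p lay between 0.0538 and 0.289. In mild drought edgeR called 0 transcripts, with 154 at an unadjusted p under 0.05 (242 expected) and a lowest adjusted p of 0.0889. DESeq2 called 13, 31 and 20 transcripts in mild drought, in severe drought and between the drought levels. On simulated data with the measured spread edgeR found 0 of the transcripts changed 2, 4 or 8-fold. At a hundredth of the measured dispersion, the square of the coefficient of variation, it found at least 94%.

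Each lncRNA transcript was paired with its nearest tested gene, to ask whether neighbours move together in severe drought. Across 4743 pairs the log2 differences had a Spearman correlation of 0.282, with a p of 1e-04, the smallest that 10000 permutations can give, and 60.6% of pairs had the same sign against 49.9% for random pairs. Pairs are not independent replicates, and the deposited gene counts include reads of lncRNA transcripts with the same identifier. The permutations compare real with random pairs and do not test the water supply. Both differences of a pair come from the same libraries, so differences between libraries unrelated to drought can also move neighbours together. With pairs of the same identifier left out the correlation was 0.0959 (2529 pairs, p = 1e-04) and with the lncRNA counts subtracted it was 0.155 (4741 pairs). Over 1108 pairs within 10 kb that did not overlap it was 0.0733 (permutation p = 0.0159). Where several genes lay at the same distance, only 1 was taken. The called TCONS_00023113 was paired with SORBI_3010G232400, which overlaps it, and not with SORBI_3010G232200, whose identifier it carries. The paired gene had a log2 difference of -0.14 ± 0.36 in severe drought (adjusted p = 0.958 in edgeR).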

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

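The tests of other splits with DESeq2, and the test of whether 1 library decides the photosystem result, were chosen after the result was seen; the other tests here were planned.

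The effects of mild and of severe drought were compared directly, in the test of severe against mild drought, and 4 gene lists, with the preset correlation of camera, and 4 lncRNA transcripts differed. With an estimated correlation the adjusted p of the lists was 0.613 for photosystems, for raffinose and for C4 enzymes and 0.843 for the Calvin cycle, and fry also called 0 of them. The median log2 differences were 0.626 for photosystems and light harvesting, 0.453 for raffinose, trehalose and galactinol, 0.438 for the Calvin cycle and 0.179 for C4 mesophyll enzymes. The transcripts were TCONS_00023113 (adjusted p = 0.00894), TCONS_00024945 (adjusted p = 0.0278), TCONS_00023111 (adjusted p = 0.0278) and TCONS_00095547 (adjusted p = 0.0278), all in edgeR. The locus XLOC_003452, outside the genes tested, held 9.54% of the gene table total in mild drought 3, 10% in severe drought 2 and 17.2% in severe drought 3, above the highest control library (9.44%). Its group means were 6.25 ± 3.06%, 6.68 ± 3.97% and 11.5 ± 5.12% (SD, n = 3), with exact p of 0.9 and 0.2 against the control where the smallest possible is 0.1. Groups of 3 libraries are too small for a test of single extreme libraries, so none was made.

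Other splits of the libraries were counted beside each result. For each comparison the 6 libraries make 10 splits, which cannot give a share under 0.05 (never under 0.1), so only the values are given. With edgeR all 10 splits gave at least as many genes as the real one in each comparison, since the real count was 0 (1414, 1914 and 815 at an unadjusted p under 0.05). The highest others were 1, 0 and 0. For lncRNA transcripts 10, 2 and 1 splits gave at least as many as the real 0, 1 and 4 in mild drought, in severe drought and between the drought levels, with highest others of 3, 1 and 2. For gene lists 7, 5 and 7 splits gave at least as many as the real 4, 5 and 4, with highest others of 10, 9 and 11.

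With DESeq2, 5, 2 and 8 splits gave at least as many genes as the real 190, 311 and 16, with highest others of 856, 660 and 347. For lncRNA transcripts 10, 1 and 6 splits gave at least as many as the real 13, 31 and 20, with highest others of 40, 25 and 22. Splits calling several times the real number of genes point to a structure of the samples other than water supply. The highest other split of each comparison was taken by the number of genes at an unadjusted p under 0.05 in edgeR. In mild drought against control it put control 3, mild drought 2 and mild drought 3 together (2697 genes). In severe against mild drought it was mild drought 2, severe drought 1 and severe drought 2 (2397). In severe drought against control it was control 3, severe drought 1 and severe drought 2 (2342). Over all 3 water levels, genes were tested with an F test of limma-trend on log2 CPM instead of edgeR. Of 100 splits drawn from those possible, the real one included, 14 gave at least as many genes at an unadjusted p under 0.05 as the real 1557. The highest other gave 3566, so chance is not excluded for that count.

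The higher photosystem list in severe than in mild drought was weighed further. Of its 66 members, 45 are named as chloroplastic, chlorophyll-binding or light-harvesting proteins, and their median log2 difference was 0.708 ± 0.058 (43 above 0). For the other 21 it was 0.45 ± 0.12 (20 above 0). These SE values treat genes as independent and do not measure the spread between libraries. The shift was not confined to the other 21, so nuclear copies of plastid genes are argued against as the whole cause. The highest adjusted p of camera over the 9 fits that left out 1 library was 5.7e-05 with the filter applied anew in each fit. With the same genes kept it was 0.000121 (without severe drought 2), so no single library decided the call. Among the 10 splits, 2 gave a camera p at least as small as the real 3.74e-12 (smallest other 7.24e-14), and these splits cannot give a share under 0.05. An effect of severe drought on these genes stays open and was not tested apart from the comparison itself, and so does a difference in leaf age or position, which the labels do not give.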

How the results depend on the processing

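The tests with voom, a surrogate variable, all entries of the gene table, subtracted lncRNA counts, sums per gene identifier or membership by the whole description, the DESeq2 overlap, and the fits without 1 library on unchanged genes, were chosen after the result was seen.

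In the order mild drought, severe drought and severe against mild drought, edgeR called 0, 0 and 0 genes (1414, 1914 and 815 at an unadjusted p under 0.05) and 0, 1 and 4 lncRNA transcripts, and camera 4, 5 and 4 lists. DESeq2 called 190, 311 and 16 genes and 13, 31 and 20 lncRNA transcripts, and shared 105 genes between both drought levels where edgeR shared 0. With no filter the lncRNA counts were 20, 36 and 29; a mean of at least 1 CPM gave 3 in severe drought. Only the 6 libraries compared gave 2 genes in severe drought, and 3, 0 and 0 lncRNA transcripts. FPKM with limma-trend gave 2 genes in mild drought and 1 and 2 lncRNA transcripts in mild and severe drought, whether 0.1 or 1 was added; the 2 in severe drought were both down with 0.1 added, and 1 up and 1 down with 1 added. Voom with sample quality weights gave 1 gene in mild and 4 in severe drought. Summed per gene identifier, 0 lncRNA loci were called in severe drought and 0 between the drought levels. Lists numbered 0, 0 and 0 with an estimated correlation and with directional fry, and 2 and 3 in mild and severe drought by the whole description. Fry for changes in either direction called 4, 4 and 0 lists, which were heat shock, abscisic acid signalling, proline and the Calvin cycle in mild drought (adjusted p = 0.0139, 0.00137, 0.00101 and 0.0152) and heat shock, nitrogen assimilation, abscisic acid signalling and proline in severe drought (0.00478, 0.0304, 0.00478 and 0.00101). The label number as a replicate block gave 0, 0 and 0 genes, 0, 0 and 0 lncRNA transcripts and 5, 5 and 4 lists; the numbers did not pair the libraries, since 3 of 9 correlated best with a library of their own number. Leaving out 1 library gave 0 to 1 genes in mild and in severe drought (1 without mild drought 3), 0 to 5, 0 to 4 and 0 to 6 lncRNA transcripts (the highest without severe drought 1), 2 to 7, 4 to 6 and 2 to 8 lists, and 0 to 1 shared genes. The other alternatives left each count within 1.5 times its value. For 70 pairs of a named gene and a comparison, 0 of 1537 values over the alternatives changed direction. This covers only those 70 and not every gene given above. Why the counts moved was not tested.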

Other observations

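The tests of low depth, of severe drought, of leaf growth stage and of mixed-up labels were chosen after the result was seen; the others here were planned.

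In severe drought 1, 64 genes on 9 chromosomes or scaffolds had no count although each had at least 5 CPM in the 8 other libraries. Besides Xa21 they included the putative disease resistance protein RPP13-like 1 (SORBI_3002G013800, mean 50.6 CPM in the other libraries), the chloroplast kinase ABC1K7 (SORBI_3001G280100, 94.7 CPM) and ureide permease 1 (SORBI_3010G115900, 27.1 CPM). Of the 19 with a protein name, 5 were disease resistance proteins or receptor-like kinases. The share of such proteins among all named genes was not counted, so the 5 are not read as an excess. Low depth is argued against by its total over the genes, 1.49 times that of the lowest other library, since 5 libraries with lower totals lacked at most 1 such gene each. Severe drought itself is argued against by 67 genes at 0 in severe drought 1 and chosen without severe drought 2 and 3. Their median log2 ratio of those 2 libraries to the controls was -0.0308 ± 0.055, an SE over genes and not over libraries. Also at 0 in severe drought 1 alone were 65 lncRNA loci, against at most 2 in any other library. A candidate explanation is that this library came from a plant line lacking these segments or carrying diverged copies; no variant calls were at hand to test that further.

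Libraries of the same water supply differed about as much as libraries of different supply. Time of day at harvest is argued against by the circadian clock list, whose within-group spread lay at percentile 3.35 of random lists of equal size and expression. Mixed-up control and drought labels were weighed with P5CS2, whose lowest drought library was 7.4 times its highest control library (127 against 17.1 CPM). This gene was picked after its levels under these labels were seen, so the ratio is not an independent check of them. The cell wall loosening list, of genes active in growing tissue, lay at percentile 100, with a median SD of 1.31 where random lists had 0.716, but so did 8 other lists, among them photosystems, class III peroxidases, cuticular wax and NAC factors. The list of histones and DNA replication, also of growing tissue, lay at 89.8 (adjusted p = 0.155), so a difference in growth stage between the libraries stays open and is not singled out.

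The cuticular wax and cutin list did not pass in mild or severe drought (adjusted p = 0.28 and 0.206). Its median log2 CPM difference was -0.02 and 0.12, with 29 and 31 of 59 members above 0 (34 and 32 by the log2 differences of edgeR), and 0 members passed when adjusted over the list alone. DESeq2 called 3 members up in mild drought, and 3 up and 1 down in severe drought. By DESeq2, non-specific lipid-transfer protein 1 (SORBI_3008G030900) rose from 1090 CPM in the control to 2712 in mild and 3682 in severe drought (adjusted p = 0.0329 and 0.000339). Of the counts of another of the 3, SORBI_3008G030801, named non-specific lipid-transfer protein 2, 99.7% were also counted for lncRNA transcripts of the same identifier. A very-long-chain aldehyde decarbonylase of the GL1 family (SORBI_3003G173700), an enzyme of wax alkane synthesis, rose by DESeq2 from 31.2 to 216 and 290 CPM (adjusted p = 0.0298 and 0.00396).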
